A study of Homo sapiens with 20 samples.

How the data were processed

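The series profiles H3K4me3 in WM164 melanoma cells by chromatin immunoprecipitation and sequencing. It lists 20 samples, of which 10 are H3K4me3 libraries with a peak list and 10 are inputs, whose data were not used here. Per the labels' protocols, 15 µg of chromatin was used per reaction, the drug was renewed every 3 days, and the libraries were sequenced over 8 lanes as single reads of 50 bp. Fixation in 4% paraformaldehyde for 10 minutes is stated for the parental, colony and resistant cells, and the conditions for the transgene cells are not given in the sources used here. Groups and replicate numbers came from the sample titles. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

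The authors deposited 1 list of peaks per library. The submitters' processing notes name BWA, SAMtools, MACS2 2.1.2 and deepTools 2.5.4 and the builds GRCh37 and hg19, without saying which step used which. The start and end positions of each deposited peak are in bases, with chromosome names in the GRCh37 style, and were turned into positions counted from 1. The deposited score is 10 times the −log10 q-value, cut to a whole number, except for 8 peaks of colony 2, 1 of resistant 1 and 4 of GFP 1. The deposited fold is the authors' ratio of the peak summit over the local background of that library. The deposited −log10 p-value and −log10 q-value belong to the same summit. These values are the authors' own and were used to describe, rank or filter peaks within a list. Peaks were called for each library separately, not on pooled samples. How the inputs and duplicate reads were treated is not given in the sources used here.

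The lists hold no read counts, so the depth is known only as far as the peak statistics imply it. Peaks with −log10 p below 25 were taken at regular steps through each list, 4008 to 5448 per library. Their fold and p-value were solved for the summit pileup and background, under the Poisson test that MACS2 applies with 1 added to both. At least 99.6% of these peaks in every library gave a whole-number pileup within 0.0005 in −log10 p. The 1st percentile of the solved backgrounds, a low value and not a typical one, was divided by the length of the shortest peak. This gave the implied reads per kb. That value assumes that the shortest peak equals the fragment length.

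Peaks on the 22 autosomes and X were analysed, and 589 of 306884 peaks on other sequences were left out of the comparisons. The annotation at hand belongs to another build, and coordinates were not converted between builds. The planned comparisons at promoters and the tests of gene lists were therefore replaced by the fallback fixed with them. Peaks of all 10 libraries that overlapped or lay within 1000 bp were merged into regions. A region was gained when both libraries of a group and neither control library had a peak in it, and lost in the reverse case. Counts are set beside those from splits of the same 4 libraries that mix the groups. There are only 3 such splits with the real one, too few for a test. Chromosome bands and their stain came from the hg19 band table of circlize 0.4.16, and every peak ended within the chromosome lengths of that table.

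Covered length was tested with limma 3.58.1 in R 4.3.3 on log2(bases under peaks + 200). Each library was centred on its median over the regions covered in all 10 libraries, and regions with a peak in at least 2 libraries entered. The fit had 5 group means, eBayes with a trend, and Benjamini-Hochberg adjustment within each comparison, with a threshold of 0.05. Log2 changes are on this scale. They depend on the added 200 bp where a group has no peak, so covered bases are given for those regions in place of a change. A region empty in both libraries has no measured spread, and its standard error then rests on the other groups and on the spread shared over regions. Jaccard indices were computed on covered bases. Overlaps between drug and transgene changes were tested with Fisher's exact test in scipy 1.17.1. For the overlap between colony and resistant changes, unchanged libraries were drawn 100 times from the rates at which 1 parental list misses peaks of the other, by strength. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

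The regions named for each comparison are the 5 largest rises and 5 largest falls past the threshold, and the 5 gained and 5 lost regions with the highest mean −log10 q in the group that has them. This rule, the tests and most alternatives were fixed before the data were examined. The alternatives were a stricter peak threshold (−log10 q of 10 or more), lists cut to equal length, an overlap of at least 200 bp, merging of overlapping peaks only, other pseudocounts (50 and 1000 bp), no centring, no filter, regions present in all libraries, separate fits, the replicate number as a block, no trend, and leaving out each library. The scripts were tested on simulated data. In 23153 simulated regions modelled on colony against parental, limma recovered 23.9% of changes of 0.5, 46.3% of changes of 1 and 86.4% of changes of 2 on the log2 scale, with 0 false calls. These limma simulations used normal noise of the fitted spread and had no libraries without peaks. Their 0 false calls therefore do not give the error rate in the real lists. In 600 simulated sites every seeded gain and loss was recovered.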

Results

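WM164 is a human melanoma cell line that carries a mutant BRAF kinase, and dabrafenib is a BRAF inhibitor. H3K4me3, trimethylation of histone H3 at lysine 4, marks the promoters of active genes and was mapped by chromatin immunoprecipitation and sequencing. The peak lists of 10 H3K4me3 libraries were analysed, 2 in each of 5 groups: parental cells given DMSO for 3 days, colonies that persisted through 45 days in 50 nM dabrafenib, resistant cells kept in the same dose for more than 90 days, and cells overexpressing GFP or the NRAS Q61K oncoprotein, an activated form of the RAS protein upstream of BRAF. The design sets long drug exposure beside oncogene expression as conditions that may alter H3K4me3. All positions are in GRCh37. Genes could not be placed on that build here, so each region is named by its position and chromosome band.

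Drug-treated cells had fewer H3K4me3 peaks than parental cells, and the loss of peaks was larger than the loss of marked sequence. On the autosomes and X, parental lists held 29662 ± 571 peaks (SD, n = 2), colony lists 21491 ± 117 and resistant lists 19256 ± 205. Those peaks covered 43.0 ± 3.27 Mb in parental, 40.8 ± 0.853 Mb in colony and 34.6 ± 0.746 Mb in resistant cells. Colony coverage thus differed from parental by less than the SD of the parental pair, and resistant coverage lay below both parental libraries. GFP lists held 43591 ± 2524 peaks over 46.8 ± 0.0449 Mb, and NRAS Q61K lists 39149 ± 2121 peaks over 46.5 ± 2.75 Mb, so those 2 groups differed in covered sequence by less than the spread of the NRAS Q61K pair. With 2 libraries against 2, no exact two-sided permutation test can give a p below 0.333, and none was run on these totals. The lists hold no read counts. The background implied by the peak statistics was 24.8 and 19.7 reads per kb in the parental libraries, 15.7 and 14.5 in colony, 19.1 and 19.3 in resistant, 22.9 and 17.7 in GFP and 25.3 and 22.5 in NRAS Q61K libraries. The shortest peak, which follows the fragment length, was 191 ± 15.6 bp in parental, 283 ± 1.41 bp in colony and 256 ± 0.707 bp in resistant lists. In GFP and NRAS Q61K lists it was 148 ± 7.78 and 152 ± 1.41 bp. It was thus longest in the drug groups, which had the fewest peaks, and least in the transgene groups, which had the most. Fragment length and treatment therefore cannot be told apart as sources of the peak numbers.

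Merging the peaks of all libraries gave 31428 regions with a median length of 1140 bp, of which 12087 had a peak in all 10 libraries. Replicate lists shared a Jaccard index of 0.813 ± 0.0179 (SD, 5 pairs; range 0.790 to 0.839). In the comparisons made here, each pair of libraries from different groups fell below that range: 0.737 ± 0.00453 for colony against parental, 0.692 ± 0.0169 for resistant against parental, 0.693 ± 0.00454 for resistant against colony, 0.771 ± 0.0102 for NRAS Q61K against GFP and 0.769 ± 0.0138 for GFP against parental (SD, 4 pairs each). That held under neither alternative tried. With the stricter peak threshold parental 1 with GFP 1 reached the lowest replicate pair (each 0.840), and with lists of equal length GFP 1 with NRAS Q61K 1 and 2 did so (each 0.832). Outside these comparisons, parental 1 against NRAS Q61K 2 reached 0.793, within the range of the replicates.

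Colonies lost H3K4me3 at many more regions than they gained it. A peak was present in both parental and neither colony library at 2620 regions, 15.6% of the 16832 regions marked in both parental libraries. The reverse was seen at 190 regions, 1.71% of the 11097 unmarked in both. Those 11097 are regions where some other library had a peak, so the shares gained depend on the libraries merged. The broadest loss was at 9p21.3 (chromosome 9, 22209133 to 22229024), where 14592 ± 706 bp lay under peaks in parental cells (n = 2) and none in either colony library (limma adjusted p = 9.62e-11). Losses of the same kind lay at 7p21.2 (chromosome 7, 15593418 to 15602347; 7733 ± 169 bp in parental, adjusted p = 1.33e-08), 8q24.21 (chromosome 8, 127840458 to 127847405; 6514 ± 369 bp, adjusted p = 9.14e-08), 10p13 (chromosome 10, 13743469 to 13751409; 6323 ± 501 bp, adjusted p = 1.33e-08) and 6p21.31 (chromosome 6, 34983866 to 34992515; 6118 ± 218 bp, adjusted p = 3.44e-08), each with no peak in either colony library. Among the lost regions with the strongest parental peaks were also 2q37.1 (chromosome 2, 231768378 to 231774715; 4914 ± 66.5 bp), 8q22.2 (chromosome 8, 101514095 to 101520138; 4602 ± 289 bp) and 1p31.3 (chromosome 1, 66796139 to 66802746; 5581 ± 29.0 bp).

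New H3K4me3 in colonies appeared at 7q22.2 (chromosome 7, 103968533 to 103973028), with 3706 ± 546 bp under peaks against none in parental cells (adjusted p = 5.45e-05), and at 1p13.3 (chromosome 1, 111738998 to 111743607), with 3712 ± 980 bp (adjusted p = 1.66e-05). The gains at 11p15.2 (chromosome 11, 15865349 to 15870902; 5292 ± 242 bp, adjusted p = 5.62e-05), 8q22.2 (chromosome 8, 99385255 to 99389706; 4337 ± 28.3 bp, adjusted p = 4.84e-06), 19q13.12 (chromosome 19, 38084351 to 38086904; 2426 ± 27.6 bp, adjusted p = 8.70e-05) and 8q13.2 (chromosome 8, 70378370 to 70380466; 1971 ± 148 bp, adjusted p = 2.44e-04) were likewise unmarked in both parental libraries. The longest gain, at 1p36.33 (chromosome 1, 564440 to 570460; 5403 ± 199 bp, adjusted p = 4.05e-05), lies where the nuclear genome holds a near-identical copy of mitochondrial DNA, so its reads cannot be assigned with certainty.

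The counts exceeded those of splits that mixed parental and colony libraries, in which 35 to 122 regions were gained or lost. Limma on covered length called 994 regions wider and 3871 narrower in colonies among 23153 tested. Most losses were of weak regions: 2340 of the 2620 lay in the weakest quartile of parental regions, of which 55.6% were lost, against 0.143% of the strongest quartile. With lists of equal length the counts became 1164 lost and 366 gained. With peaks of −log10 q of 10 or more 1001 were lost, of which 384 had no colony peak of any strength. The others kept a weaker peak in a colony library. A single library in place of a pair raised gains to 336 without parental 1, 506 without colony 1 and 424 without colony 2, and losses to 4749 without parental 2, while 654 regions were wider without colony 1.

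**Figure D1:**
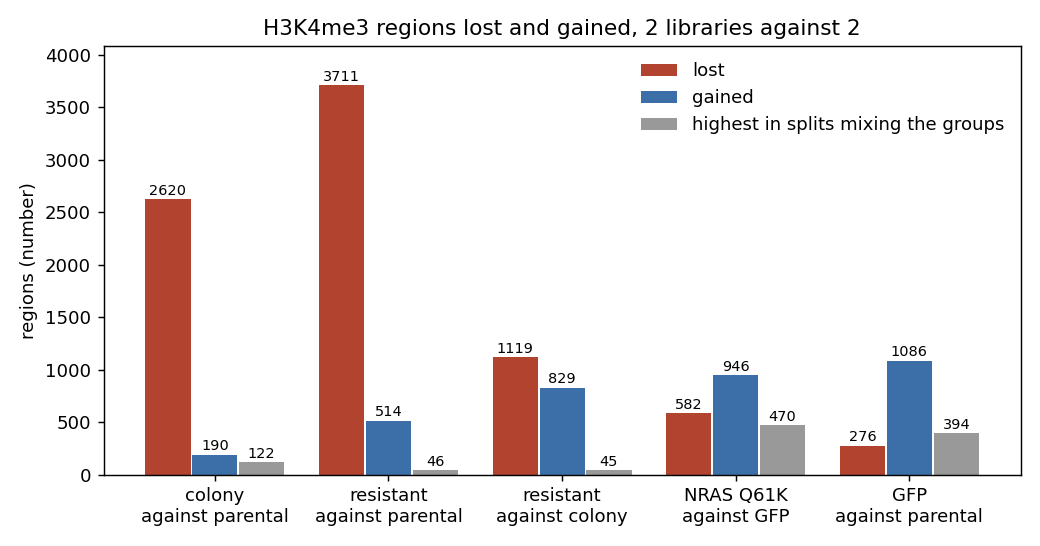
Bars give the number of merged H3K4me3 regions lost (present in both control libraries and in neither of the other group) and gained (the reverse) in each comparison, with the highest count of either kind in splits that mix the groups. Losses exceed gains in colony (2620 against 190) and resistant cells (3711 against 514) set against parental cells, and gains exceed losses for NRAS Q61K against GFP (946 against 582).

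Resistant cells lost more regions than colonies did and also gained more. Relative to parental cells 3711 regions were lost (22% of those marked in both parental libraries) and 514 were gained (4.63% of those unmarked in both). The strongest losses were at 11q13.3 (chromosome 11, 70085144 to 70091391), where 4886 ± 462 bp were covered in parental cells and none in either resistant library (adjusted p = 3.36e-08), 15q25.1 (chromosome 15, 80601127 to 80604167; 2193 ± 50.2 bp, adjusted p = 1.42e-06), 20q13.31 (chromosome 20, 56170802 to 56177828; 4984 ± 204 bp, adjusted p = 5.60e-08) and 7q22.2 (chromosome 7, 104434253 to 104448253; 8452 ± 818 bp, adjusted p = 6.43e-09). All of those regions were covered in both colony libraries. By contrast a second region of 20q13.31 (chromosome 20, 55353813 to 55359620), covered over 4690 ± 330 bp in parental cells, was empty in both resistant libraries and colony 2 and kept 376 bp in colony 1. Wide falls also occurred at 8p12 (chromosome 8, 29601211 to 29612888; 7889 ± 488 bp in parental, adjusted p = 5.60e-08) and at 3 regions at or next to centromeres, 2p11.2 (chromosome 2, 90371503 to 90394577; 12927 ± 597 bp), 2p11.1 (chromosome 2, 91595109 to 91616085; 11878 ± 1623 bp) and 4p11 (chromosome 4, 49638952 to 49659920; 8764 ± 989 bp), where repeats share reads.

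Regions that rose in resistant cells included 2 of 15q26.3. One (chromosome 15, 101418376 to 101425549) had 6474 ± 651 bp under peaks in resistant cells and none in any library of the other 4 groups (adjusted p against parental = 2.54e-06). The other (chromosome 15, 101336454 to 101344040) had 6398 ± 59 bp in resistant cells, 224 bp in parental 2, 6059 and 5405 bp in the GFP libraries and 6548 and 5690 bp in the NRAS Q61K libraries, so it belongs to the wider regions and not to the strict gains. Gains found in the resistant pair alone also lay at 14q21.1 (chromosome 14, 42071272 to 42079827; 6747 ± 243 bp, adjusted p = 2.30e-06) and 12q21.31 (chromosome 12, 81328669 to 81333505; 4447 ± 260 bp, adjusted p = 4.02e-06). Those at 19q13.2 (chromosome 19, 42055598 to 42060072; 4150 ± 114 bp, adjusted p = 3.27e-05) and 1q32.1 (chromosome 1, 201366341 to 201370330; 3739 ± 273 bp, adjusted p = 3.28e-05) were marked elsewhere only by 221 and 205 bp in NRAS Q61K 1. The gains at 1p36.32 (chromosome 1, 4035383 to 4039549; 3536 ± 132 bp, adjusted p = 6.94e-06) and 7q21.13 (chromosome 7, 89748272 to 89750299; 1580 ± 282 bp, adjusted p = 4.68e-04) were present in both colony libraries too.

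Mixed splits of the same libraries gave 4 to 46 regions gained or lost. Limma called 1836 regions wider and 4779 narrower. At regions covered in all 10 libraries, the centring applied to the resistant libraries was -0.19 and -0.22 on the log2 scale, and without it the split was 882 wider and 7279 narrower, so the widths are relative to that general narrowing. Of the lost regions 3205 were in the weakest parental quartile, where 76.1% were lost, against 0.166% in the strongest. Equal list lengths reduced the losses to 1289, with 724 gains. The stricter peak threshold gave 1310 losses, of which 687 had no resistant peak of any strength. Losses rose to 5995 without parental 2, wider regions fell to 894 and 888 without resistant 1 and 2, and narrower regions fell to 3176 without resistant 2.

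**Figure D2:**
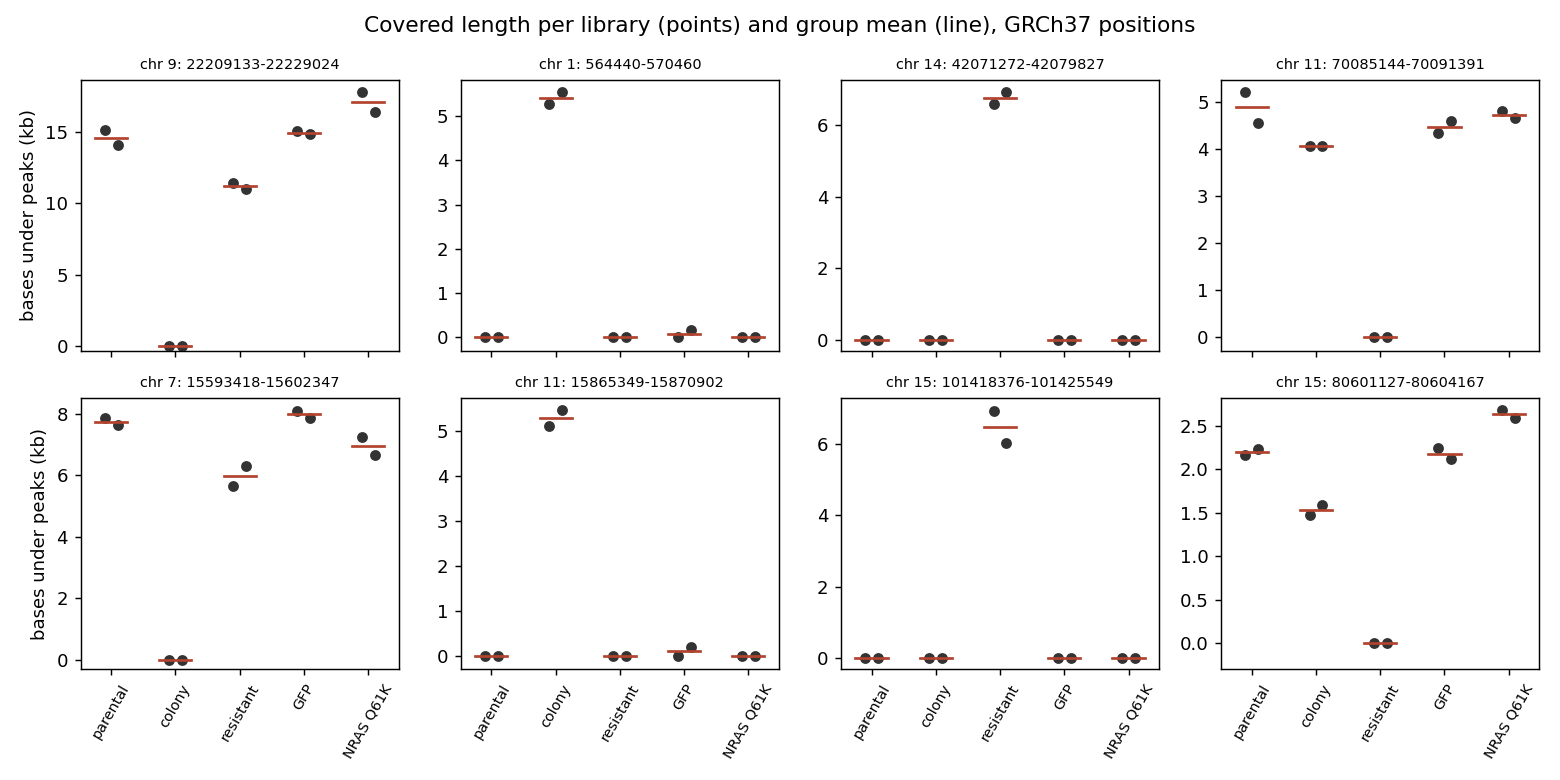
Points give the bases under H3K4me3 peaks (kb) in each library and lines the group means, for 8 named regions in GRCh37 positions, over parental, colony, resistant, GFP and NRAS Q61K cells. The columns show, from left to right, falls in colony, rises in colony, rises in resistant and strong losses in resistant cells; the 9p21.3 region has 0 bp in colony and 11213 bp on average in resistant libraries.

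Set directly against colonies, resistant cells had H3K4me3 at some regions that were empty in colonies and lacked it at others. The labels do not say whether the resistant cells came from such colonies. The 9p21.3 region had 11213 ± 343 bp under peaks in resistant cells and none in colonies (adjusted p = 1.21e-10), and the 7p21.2 region had 5973 ± 473 bp (adjusted p = 1.50e-08). Regions at 10q22.3 (chromosome 10, 81158088 to 81164228; 4789 ± 888 bp, adjusted p = 1.01e-06) and 22q11.21 (chromosome 22, 20197654 to 20200429; 2356 ± 169 bp, adjusted p = 3.16e-06) were also empty in both colony libraries and marked in all 8 others. In the opposite direction, 15q13.3 (chromosome 15, 31386359 to 31394526) was covered over 7045 ± 432 bp in colonies, 219 and 180 bp in the parental libraries and nowhere in resistant cells (adjusted p = 2.24e-06). Regions at 2q33.1 (chromosome 2, 202278471 to 202286179; 7314 ± 559 bp in colony, adjusted p = 2.58e-08), 1p36.31 (chromosome 1, 6084513 to 6091260; 6471 ± 5.66 bp, adjusted p = 2.58e-08), 9q34.3 (chromosome 9, 141061588 to 141069095; 6077 ± 68.6 bp, adjusted p = 2.58e-08) and 3q25.32 (chromosome 3, 157096229 to 157100082; 3751 ± 146 bp, adjusted p = 1.07e-07) had peaks in every library except the resistant pair.

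In that comparison 829 regions were gained and 1119 lost, against 15 to 45 in mixed splits. Of the 829 gains, 291 were marked in both parental libraries and 441 in neither. Of the 1119 losses, 874 were marked in both parental libraries. Limma called 2540 regions wider and 2662 narrower with centring, and 1420 and 5305 without it. The excess of losses was not kept under 2 other settings. The stricter peak threshold gave 566 gains and 542 losses, and equal list lengths 898 and 880. Wider regions outnumbered narrower ones under both (1682 against 1541, and 2345 against 2096). They also did so with a pseudocount of 1000 bp (2662 against 2423), among regions in all 10 libraries (1879 against 1839) and without colony 2 (2251 against 2193). Losses rose to 1956 without colony 1 and 1724 without colony 2, and wider regions fell to 1640 without resistant 1.

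Both the losses and the gains of the drug groups overlapped by more than independent lists would. Of the regions lost in colonies, 2178 (83.1%) were also unmarked in both resistant libraries and 291 (11.1%) were marked in both. Of the 190 colony gains, 44 (23.2%) were marked in both resistant libraries and 137 in neither. Independent lists of the same sizes would share 578 losses and 8.80 gains, and lists drawn within bins of equal parental strength would share 1925 losses. Groups simulated as unchanged against the same 2 parental libraries shared 70.6 losses and 3.59 gains on average over 100 draws, with highest values of 89 and 8. Part of the excess may come from the shared controls, which are too few to be split. The simulated libraries missed regions independently and at the rates of the parental pair. They held no drop in peak number shared by the drug libraries, so the excess of losses alone cannot show a change in the mark. Across the 23153 tested regions, which are not independent replicates, the covered-length changes correlated with r = 0.538 (Spearman's rho 0.518), where simulated unchanged groups gave 0.501 (0.483 to 0.521); the covariance was 0.395 against 0.0419 simulated, a difference of 0.353. With lists of equal length 602 losses and 99 gains were shared.

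**Figure D3:**
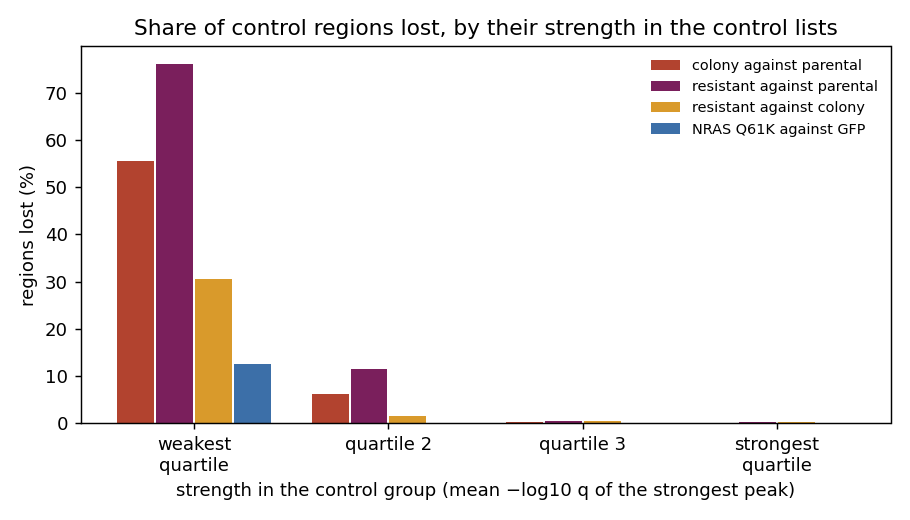
Bars give the per cent of regions marked in both control libraries that were lost in each comparison, by quartile of their strength in the control group (mean −log10 q of the strongest peak). Losses concentrate in the weakest quartile, with 55.6% for colony and 76.1% for resistant against parental, and stay below 0.5% in the 2 stronger quartiles of all 4 comparisons.

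NRAS Q61K cells lost fewer strong regions relative to GFP cells than the drug groups lost relative to parental cells. The order of strong gains depended on the way of counting. Where the control libraries had no peak of any strength, NRAS Q61K cells had about as many as colonies and fewer than resistant cells. With only peaks of −log10 q of 10 or more kept in every library, they had the most (538, against 134 in colonies and 351 in resistant cells). These numbers were not tested against each other. The clearest gain was at 4p15.32 (chromosome 4, 16073332 to 16078131), with 4050 ± 375 bp under peaks in NRAS Q61K cells and none in GFP cells (adjusted p = 2.01e-04); the region was also marked in both parental libraries, over 2858 and 2056 bp. The regions at 1p13.2 (chromosome 1, 114521629 to 114524994; 2970 ± 300 bp, adjusted p = 2.01e-04), 2p22.2 (chromosome 2, 37539461 to 37543154; 2616 ± 362 bp, adjusted p = 3.37e-03) and 10q23.1 (chromosome 10, 87540796 to 87543666; 2602 ± 381 bp, adjusted p = 2.09e-03) were likewise empty in GFP and marked in parental cells. At 13q13.1 (chromosome 13, 33755377 to 33761131) 2819 ± 513 bp were covered in NRAS Q61K and none in GFP cells (adjusted p = 2.01e-04), while parental libraries had 252 and 258 bp and resistant libraries 5535 and 5523 bp. A region of 1q21.3 (chromosome 1, 153012501 to 153013681) was marked in the NRAS Q61K pair alone, over 856 ± 233 bp (adjusted p = 1.36e-03). At 19q13.2 (chromosome 19, 43028685 to 43033508) coverage was 3950 ± 805 bp against 80 ± 113 bp in GFP (log2 change 3.98, SE 0.29, adjusted p = 6.89e-04), with 1747 and 1495 bp in parental and 600 and 887 bp in colony libraries. Most of the largest falls lay in centromeric bands. Xp11.1 (chromosome X, 58563746 to 58581829) had 639 ± 654 bp against 7860 ± 4145 bp in GFP (log2 change -3.38, SE 0.65, adjusted p = 0.0190), and Xq11.1 (chromosome X, 61694081 to 61700841) had none against 2017 ± 1504 bp (adjusted p = 6.30e-03). 5q11.1 (chromosome 5, 49429144 to 49441616) had 288 ± 49.5 bp against 4684 ± 2138 bp (log2 change -3.21, SE 0.55, adjusted p = 0.0125), and 22q11.1 (chromosome 22, 16683132 to 16687004) had none against 1244 ± 65.8 bp (adjusted p = 3.42e-04). The fall at 14q11.2 (chromosome 14, 19136628 to 19140500), in a band not stained as centromeric, was of the same size, from 1241 ± 36.8 bp to none (adjusted p = 3.42e-04). The regions at 14q11.2 and 22q11.1 were both 3873 bp long and unmarked in every library except the GFP pair. They may share reads and so not be separate falls, which was not tested. Of 251 values under other settings for the 17 regions named by rule in this comparison, 42 lost the call and 2 reversed. Among the regions above, calls at Xp11.1, Xq11.1 and 5q11.1 were lost under several settings, with a reversal at Xq11.1 when lists had equal length. The call at 19q13.2 was lost with the stricter peak threshold and that at 2p22.2 without NRAS Q61K 1, and the others were kept throughout.

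In all 946 regions were gained and 582 lost, against 126 to 470 in splits that mixed NRAS Q61K and GFP libraries. Of these, 45 gained and 4 lost regions had −log10 q of 10 or more in both libraries with the peak, against at most 1 in mixed splits. The other pair had no peak of any strength in them. Counted in the same way against parental cells, colonies had 39 gains and 384 losses and resistant cells 182 and 687. Of the gains, 126 were marked in both parental libraries and 596 in neither. Limma called 1171 regions wider and 504 narrower, but a fit to the 2 transgene groups alone called 122 and 10, with 2 in place of 5 residual degrees of freedom and 21556 in place of 23153 regions tested. The joint fit gave 71 wider and 48 narrower regions without NRAS Q61K 1, 134 and 49 without NRAS Q61K 2, and 106 and 72 narrower without GFP 1 and GFP 2. Libraries outside the comparison mattered too. Without resistant 1 and 2 there were 627 and 627 wider and 132 and 133 narrower regions. Without colony 1 and 2 there were 260 and 261 narrower ones. Gains rose to 1500 and 1515 without GFP 1 and 2 and to 1983 and 3301 without NRAS Q61K 1 and 2, and losses to 4147, 1741 and 1149 without GFP 1, GFP 2 and NRAS Q61K 1. Losses thus outnumbered gains when either GFP library was left out.

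Most of the few NRAS Q61K losses that could be compared were also drug losses, whereas the tests of shared gains could not decide. Among the 16036 regions marked in all parental and GFP libraries, 2091 were lost in colonies and 76 with NRAS Q61K, and 64 in both (Fisher's exact test, two-sided, odds ratio 36.7, adjusted p = 2.55e-44 over 8 tests); lists drawn within bins of equal strength would share 51.2. For resistant cells the numbers were 3050, 76 and 71 (Fisher's exact test, odds ratio 61.9, adjusted p = 1.83e-44), with 65.2 expected at equal strength. Strength alone would thus give most of the shared losses, and the excess over it was not tested. Regions are not independent in any of these Fisher tests. Of the 4483 regions unmarked in those controls, 20 were gained both in colonies and with NRAS Q61K (Fisher's exact test, odds ratio 1.05, adjusted p = 0.803). Gained both in resistant cells and with NRAS Q61K were 42, against 60.1 for independent lists (Fisher's exact test, odds ratio 0.643, adjusted p = 9.26e-03). Each of the 4483 was made by a peak in a colony, resistant or NRAS Q61K library. Regions empty in all groups are thus missing, which lowers the apparent overlap, and these tests cannot decide whether gains were shared. Changes in opposite directions could be compared only where parental and GFP cells differed, at 276 regions marked in parental cells alone and 1086 marked in GFP cells alone, and no expectation at equal strength was computed for them. Regions gained with NRAS Q61K and lost in colonies numbered 73, against 84 (odds ratio 0.484, adjusted p = 9.26e-03), and those lost in resistant cells 86, against 101 (odds ratio 0.239, adjusted p = 2.18e-05). Regions lost with NRAS Q61K and gained in resistant cells numbered 3, against 10.2 (odds ratio 0.210, adjusted p = 6.75e-03). For colonies there were 2, against 5.62 (odds ratio 0.266, adjusted p = 0.0799). Across regions the covered-length changes correlated with r = 0.0169 (rho -0.0436) for colony and r = 0.0809 (rho 0.0602) for resistant cells. Equal list lengths gave 16 and 28 shared losses.

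The control groups themselves differed. GFP cells gained 1086 regions and lost 276 relative to parental cells, against 106 to 394 in mixed splits, and most of these were weak, with 26 gains and 2 losses at −log10 q of 10 or more in both libraries that had them. Limma called 618 regions wider and 392 narrower in GFP cells, but the direction was not stable. Wider and narrower regions were 125 and 329 with lists of equal length, 201 and 437 with a pseudocount of 1000 bp, 267 and 299 without a filter, and 29 and 102 among regions in all 10 libraries. Equal list lengths also turned the gains and losses, to 342 and 714. Gains rose to 1927 without parental 1, 5155 without GFP 1 and 2545 without GFP 2, and losses to 657, 1230, 557 and 515 without parental 1, parental 2, GFP 1 and GFP 2. Wider regions fell to 404, 194 and 146 without parental 2, GFP 1 and GFP 2, and narrower ones to 188, 220 and 198 without parental 1, GFP 1 and GFP 2. Leaving out a library of another group moved them as well. Without resistant 1 and 2, 81 and 82 regions were wider and 88 and 88 narrower. Without colony 1 and 2, 212 and 213 were wider and 285 and 283 narrower.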

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

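The tests of explanations in this part were chosen after the results were seen. Several of the named regions changed differently in colony and resistant cells, as a direct limma comparison of the 2 groups showed; the differences below are resistant minus colony means of bases under peaks. Regions marked in colonies and not, or less, in resistant cells were 1p36.33 (-5402.5 bp), 11p15.2 (-5292 bp), 8q22.2 (chromosome 8, 99385255 to 99389706; -4337 bp), 1p13.3 (-3712 bp), 19q13.12 (-2425.5 bp) and 8q13.2 (-1971 bp), all unmarked in parental cells. Regions marked in parental cells and colonies but empty in resistant cells were 7q22.2 (chromosome 7, 104434253 to 104448253; -9788 bp), 2p11.1 (-5027 bp), 2p11.2 (-4769 bp), 11q13.3 (-4069 bp), 8p12 (-3743 bp), 20q13.31 (chromosome 20, 56170802 to 56177828; -3560.5 bp), 4p11 (-2078.5 bp) and 15q25.1 (-1531 bp).

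Regions empty in colonies and marked in parental and resistant cells were 9p21.3 (11212.5 bp), 7p21.2 (5972.5 bp), 8q22.2 (chromosome 8, 101514095 to 101520138; 3613.5 bp), 2q37.1 (3004 bp), 10p13 (2493.5 bp), 6p21.31 (1012.5 bp) and 1p31.3 (548 bp). Regions marked in resistant cells, with little or nothing in parental cells and colonies, were 14q21.1 (6747 bp), the 2 regions of 15q26.3 (6474 and 6397.5 bp), 12q21.31 (4447 bp), 19q13.2 (chromosome 19, 42055598 to 42060072; 4149.5 bp) and 1q32.1 (3739 bp). At 1p36.32, marked in both drug groups, resistant cells had 1178.5 bp more. The adjusted p of these differences ran from 1.21e-10 at 9p21.3 to 0.0308 at 1p36.32.

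Complete losses of strong regions were few and differed between the drug groups. Colonies lost 11 regions whose weaker parental peak exceeded the median of kept regions, and 9 of them were marked in both resistant libraries; resistant cells lost 15, of which 14 were marked in both colony libraries. All 11 and all 15 were marked in the GFP and NRAS Q61K libraries. A deletion reaching the neighbouring regions would remove most neighbours too, but 8 of 22 nearest neighbours (36.4%) were lost in colonies, against 15.6% of all regions, and 7 of 30 (23.3%) in resistant cells, against 22%. That argues against such deletions at all of these regions. It cannot exclude them at some regions, since the neighbours were pooled and those of colonies were lost more often than regions at large. Deletions of single regions remain open too, as does a change in the mark itself under the drug, which was not tested.

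A signal outside the comparisons was found on the mitochondrial genome, whose DNA carries no histones. All 16569 bp lay under 1 peak in colony 1, and the same 16569 bp in colony 2. The parental lists had 12600 and 14291 bp in 12 peaks each, the GFP lists 148 and 4571 bp, and the resistant and NRAS Q61K lists none. The gain at 1p36.33 lies on a nuclear copy of mitochondrial DNA, and mitochondrial reads placed on a nuclear copy are a candidate source. The region was covered over 1 kb or more in 2 libraries, the same 2 that had the whole mitochondrial genome under 1 peak, but both cuts were chosen after the values were seen. The highest mitochondrial fold was 2.31 and 2.59 in the colony libraries and close to that in parental 2 (2.29) and GFP 2 (2.36), which had 0 and 174 bp of the region under peaks. Whether this source or a change in the drug-treated cells gave the gain cannot be told.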

How the results depend on the processing

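The alternatives without pericentromeric and variable bands and with peaks trimmed to one shortest width were chosen after seeing the data; neither moved a count by more than 1.5 times. Promoter windows, transcription start sites and gene lists were not run, since genes could not be placed. Replicate numbers were not taken to pair the samples: deviations of same-numbered libraries correlated between -0.066 and 0.077 over the tested regions, and between -0.046 and 0.125 over regions in all 10 libraries. With the replicate block, counts stayed within 1.5 times (933 wider and 3713 narrower for colony, 1768 and 4656 for resistant, 1089 and 456 for NRAS Q61K) except 324 wider for GFP against parental. Of 1003 values for 65 named regions, 959 kept direction and side of the threshold, 42 lost the call and 2 reversed, all 44 for NRAS Q61K against GFP; the reversals were Xq11.1 (chromosome X, 61694081 to 61700841) at 0.0216 (log2) with equal list lengths and 2q21.2 (chromosome 2, 133109763 to 133111855) at 0.0311 with merging of overlapping peaks only. The lack of counts limits every value to the peaks the authors called. Unless the construction of an alternative shows it, the cause was not tested.

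With −log10 q of 10 or more, fewer peaks enter: losses were 1001 for colony against parental, 1310 for resistant against parental, 542 for resistant against colony, 102 for NRAS Q61K and 118 for GFP; gains 538 for NRAS Q61K and 377 for GFP; wider and narrower regions 515 and 1530 for colony, 1094 and 2025 for resistant, 1682 and 1541 for resistant against colony, 534 and 104 for NRAS Q61K, 271 and 130 for GFP. Regions with only weaker peaks on the empty side count among these losses and gains. Similarity rose to 0.852 for replicates, 0.769 for colony, 0.728 for resistant, 0.712 for resistant against colony, 0.827 for NRAS Q61K and 0.826 for GFP. Ratios of peak numbers were 0.841 for colony over parental, 0.827 for resistant over parental, 0.982 for resistant over colony, 1.00 for NRAS Q61K over GFP and 1.13 for GFP over parental, and with peaks merged within 1 kb 0.787, 0.738, 0.939, 0.991 and 1.18, against 0.725, 0.649, 0.896, 0.898 and 1.47 for all peaks.

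For gains and losses, lists of equal length were cut to the shortest list of each comparison. That was 21408 peaks for colony, 19111 for resistant against parental or colony, 37649 for NRAS Q61K and 29258 for GFP. Covered length and similarity used 19111 peaks in every library. With lists of equal length, losses were 1164 for colony, 1289 for resistant and 714 for GFP, and gains 366 for colony and 342 for GFP. Narrower regions were 1570 for colony, 2271 for resistant and 117 for NRAS Q61K, wider ones 517 for NRAS Q61K, and wider and narrower 125 and 329 for GFP. Similarity was 0.844 for replicates, 0.762 for colony, 0.728 for resistant, 0.701 for resistant against colony, 0.826 for NRAS Q61K and 0.822 for GFP. Shared changes were 602 losses and 99 gains for colony and resistant, and 16 and 28 losses of colony and resistant with NRAS Q61K. Without centring, wider and narrower were 882 and 7279 for resistant, 1420 and 5305 for resistant against colony, 980 and 256 for GFP. Without a filter 300 regions were narrower for NRAS Q61K, and 267 wider and 299 narrower for GFP; a pseudocount of 1000 gave 197, 201 and 437. Overlap of at least 200 bp gave 352 losses for NRAS Q61K and 510 gains for GFP. Merging of overlapping peaks only gave 356 gains for colony, 1447 gains, 1418 losses and 1242 narrower for NRAS Q61K, and 2323 gains and 1701 wider for GFP. Among regions in all 10 libraries, which are fewer, 1231 were narrower for colony, 1137 wider and 1572 narrower for resistant, 208 and 26 for NRAS Q61K, 29 and 102 for GFP. Separate fits gave 122 and 10 for NRAS Q61K.

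The ranges that follow cover the libraries of the groups compared. Leaving out 1 library lets the other decide alone, so gains and losses rise by construction; for covered length the lone library is assumed to vary like the other groups. Gains ran from 218 to 506 for colony, 536 to 686 for resistant, 898 to 1126 for resistant against colony, 1500 to 3301 for NRAS Q61K and 1448 to 5155 for GFP. Losses ran from 2949 to 4749, 3889 to 5995, 1224 to 1956, 792 to 4147 and 515 to 1230 in that order. Wider regions ran from 654 to 712, 888 to 1389, 1640 to 2251, 71 to 964 and 146 to 433, and narrower ones from 2893 to 3727, 3176 to 4283, 2084 to 2303, 48 to 106 and 188 to 326. Leaving out a library of an uninvolved group moved covered-length counts by over 1.5 times only for NRAS Q61K against GFP (627 to 1371 wider, 132 to 637 narrower) and GFP against parental (81 to 766 wider, 88 to 410 narrower).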

Other observations

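The tests in this part were chosen after the results were seen. Losses were unevenly spread over chromosome bands. In dark Giemsa bands, which are relatively poor in genes, 591 of 2589 parental regions (22.8%) were lost in colonies, against 1392 of 9999 (13.9%) in light bands (Fisher's exact test over regions, which are not independent, odds ratio 1.83, p = 1.20e-26). In resistant cells the shares were 31.9% and 20.1% (Fisher's exact test, odds ratio 1.86, p = 1.45e-35). The unevenness was not limited to the drug groups. For NRAS Q61K against GFP the shares were 3.90% and 2.69% (Fisher's exact test, odds ratio 1.47, p = 1.00e-03). Dark bands held the higher share also within the weakest quartile of regions (61% against 53.1% in colonies, 81.8% against 74.9% in resistant cells) and the next quartile (9.77% against 5.82%, and 19.1% against 10.1%). In the 2 stronger quartiles of resistant cells they held the lower share, with 0.178% against 0.308% in the weaker of them and no loss in the strongest. Pericentromeric or variable bands lost 25.1% in colonies, 40.9% in resistant cells and 12.9% with NRAS Q61K, and their difference from dark bands was not tested. By chromosome arm, the highest share lost was on 21p, with 10 of 21 regions in colonies (47.6%, adjusted p = 6.40e-03 over 336 tests) and 11 of 21 in resistant cells (52.4%, adjusted p = 0.0175). The lowest was on Xq, with 18 of 281 in colonies (6.41%, adjusted p = 1.21e-04) and 29 of 281 in resistant cells (10.3%, adjusted p = 1.84e-05). The difference between colony and resistant cells on an arm was not tested. Arms were not compared at equal strength of regions, so the part of strength in these shares is not known.

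Peaks over 5 kb numbered 778 ± 227 in parental (SD, n = 2), 953 ± 58.7 in colony, 510 ± 30.4 in resistant, 833 ± 69.3 in GFP and 901 ± 144 in NRAS Q61K lists. The resistant pair (531 and 488) lay below every other library, of which the lowest was parental 2 with 617. That order did not hold for the share of each list. Such peaks made up 2.74% and 2.55% of the resistant lists, 3.21% and 2.05% of the parental and 4.26% and 4.61% of the colony lists. In GFP lists the shares were 2.11% and 1.73%, and in NRAS Q61K lists 2.47% and 2.12%. The resistant shares thus lay between those of the parental libraries, below colony and above both transgene groups.

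The excess of lost over gained regions in the drug groups could have technical sources. Fragment length, as read from the shortest peak, differed between the groups, and its effect on which regions have a peak was not tested. For resistant cells the values argue against lower sequencing depth only in relation to the shallower parental library, and only as far as the implied depth holds. Both resistant libraries had an implied depth of at least 0.970 of that library's, yet the fuller one had a peak in only 0.778 times as many regions. For colonies depth stays open. The fuller colony library had a peak in 0.826 times as many regions as that parental library, and the implied depth was down to 0.737 of it. The implied depth was higher in parental 1 (24.8 reads per kb) than in both resistant libraries. It also did not follow the number of regions in the GFP pair. GFP 2 had a peak in 23172 regions at 17.7 reads per kb, and GFP 1 in 20487 at 22.9. A lower enrichment of every region may explain the weaker losses, because 99.6% of the lost regions in colonies, and 99.6% in resistant cells, were weaker in parental lists than the median kept region; a biological loss of weak marks would give the same. For the stronger regions, the libraries of a group missed the same ones more often than by independent misses. Of 6634 stronger regions, 11 were missing from both colony libraries and 3 from 1. Independent misses at equal strength would leave 0.0477 missing from both. Of 6328 in the comparison with resistant cells, 15 were missing from both libraries and 6 from 1, against 0.0602. That cannot decide the question, because a lower enrichment shared by both libraries would also make them miss the same regions.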
